A study of Arabidopsis thaliana with 18 samples.

How the data were processed

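RNA from Arabidopsis thaliana seedlings was measured on 18 one-colour arrays, with biotin-labelled cRNA primed from poly(A) tails, per the labels' protocols. Seedlings of 10 days were taken from plates and floated for 1 h on 3 mM MES buffer, after which H2O2 was added to 20 mM or benzyl adenine (BA, a cytokinin) to 2 µM. Per the labels, treatment lasted 6 h and every solution, controls included, held 0.2% DMSO. No treatment time was recorded here for the untreated samples, so it was not checked that they were harvested with the treated ones. The 9 groups are the wild type (WT), a crf6 mutant and a line named CRF6oe, each untreated, with H2O2 and with BA, with 2 arrays in each group, as the sample titles give them. CRF6 is CYTOKININ RESPONSE FACTOR 6, a transcription factor gene of the AP2/ERF family. Nothing in the labels says whether the 2 samples of a group came from separate cultures, so every p-value here measures only the spread between these samples, which may be technical.

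The values used are the authors' deposited table of 1 value per feature and array. Its scale is not stated per the labels, and the log2 scale was taken from the deposited values themselves, whose medians ran from 4.63 to 4.98 and whose highest value was 14.26. The background correction, normalization and summary that the authors applied, and whether all 18 arrays were normalized together, are not given in the sources used here. No batch, date or array layout is given in them either. The values were used as deposited, with no further scaling. The number of arrays limits the precision that can be stated.

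Features were named through the platform's probe table. Of 38408 features, 16722 were paired with exactly 1 gene and were analysed, 759 were paired with several genes and 20927 were not listed. The 21686 features left are unnamed here and enter none of the gene counts. They were tested only in a fit of all features. Locus codes and symbols were looked up in a RefSeq gene table for TAIR10.1, where 16574 of the 16722 features matched and 148 did not. The feature with the highest mean over all arrays stood for a gene with several features, which left 16548 genes, 14786 of them named by locus code only. No named feature was paired with CRF6 (AT3G61630), so the level of the targeted gene was not analysed here and the labels of the mutant and of CRF6oe were not checked on it.

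Tests used limma 3.58.1 in R 4.3.3. A linear model with the 9 group means was fitted to all 18 arrays, which share 1 estimate of the spread with 9 residual degrees of freedom. Moderation by eBayes added 5.63 prior degrees of freedom. Each comparison was a two-sided contrast of group means. P-values were adjusted by the Benjamini-Hochberg method over the 16722 features, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors (SE) from this fit, and errors of group levels are SDs over 2 arrays. The contrasts were each treatment against untreated within a genotype, each genotype against WT within a condition and as the mean over 3 conditions, and the difference of a treatment response between a genotype and WT (the interaction). The median SE was 0.229 for 2 arrays against 2, 0.132 for a mean over conditions and 0.324 for an interaction.

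The fit was tested on simulated data with 200 of the 16722 features changed by known amounts. For H2O2 against untreated in WT it recovered 4% of changes of 0.5 on the log2 scale, 54% of changes of 1, 94% of changes of 2 and 100% of changes of 3. For the difference of the H2O2 response between crf6 and WT the corresponding shares were 0%, 16%, 64% and 92%. For the crf6 mean over 3 conditions they were 38%, 94%, 98% and 100%. False calls in these 3 contrasts were 6 of 132, 1 of 87 and 11 of 176. The simulated arrays varied independently, so these shares do not cover arrays that vary together.

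The contrasts, the gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. The rule names the 10 genes with the largest rise and the 10 with the largest fall for each treatment in WT, and 5 of each for every other contrast. It takes only called genes whose arrays do not overlap between the groups compared. Up to 4 called members of each list described, and any called cytokinin gene, were added to these. Of 26 fixed lists, the 8 with at least 4 measured members were tested with camera, at a preset inter-gene correlation of 0.01. Adjustment was over the lists within a contrast, and camera was run again with a correlation estimated for each list. These 8 hold heat shock proteins, the mitochondrial dysfunction response, antioxidant enzymes, glutathione S-transferases, the abscisic acid and dehydration response, auxin response and transport, light-harvesting and Rubisco small subunit genes, and plastid-encoded genes. The other 18 lists held fewer measured members, so only single genes of them are given. Outside the plastid list, most listed genes were not measured. Measured were 7 of 22 listed heat shock genes, 5 of 36 antioxidant enzymes, 2 of 10 type-A response regulators and 0 of 6 cytokinin response factors. Results of a list therefore cover its measured members only, not the whole list. A further 27 gene families, defined by symbol or position, were added after the first results had been seen.

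The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 30% of features, the replicate number as a block, a fit of only the arrays compared, an intensity trend in the spread prior, a threshold of at least 2-fold, and leaving out each array in turn. The fit of all 38408 features and the fit without the 6 CRF6oe arrays were added after the data had been seen. Counts given with unnamed features tested too come from the former and are still counts of named genes. When 1 array of a group is left out, the other is assumed to vary like the arrays of the other groups.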

Results

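Transcript levels of 16548 genes were measured in 10-day-old Arabidopsis seedlings of 3 genotypes, the wild type (WT), the crf6 mutant and CRF6oe, each untreated, exposed to 20 mM H2O2 or exposed to 2 µM benzyl adenine (BA) for 6 h. Per the series description, the treatments were chosen to find genes controlled by CRF6. There were 2 arrays in each of the 9 groups, 18 in all, and their number limits the precision of every comparison. Replicates of 1 group correlated over genes at r = 0.977 to 0.991. The 6 CRF6oe arrays stood apart from the rest, with r = 0.917 to 0.946 against WT and crf6 arrays, while WT and crf6 arrays correlated among themselves at 0.948 to 0.991. The highest value on an array was 14.16 to 14.26 on the CRF6oe arrays and 13.90 to 13.99 on the other 12. As CRF6oe is also a genotype, and no batch is given, genotype and array set cannot be told apart in any comparison of CRF6oe with WT.

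**Figure D1:**
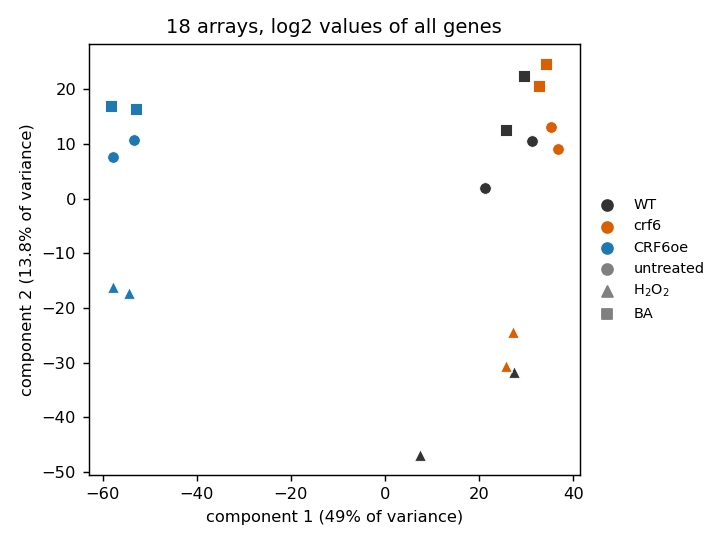
Principal components of the log2 values of all genes, with component 1 (49.0% of variance) across and component 2 (13.8%) upwards, 1 point per array, colour for genotype and shape for treatment. The 6 CRF6oe arrays lie between -58.2 and -53.0 on component 1 and the other 12 between 7.50 and 36.7, and the H2O2 arrays of each genotype lie lowest on component 2. The 7.50 is WT H2O2 replicate 1, apart from the next of the 12 at 21.2, and this array is also the lowest on component 2 (-46.9).

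In WT, 4 of the 10 largest named rises with H2O2 were small heat shock proteins, chaperones that bind unfolding proteins. AT2G29500, a class I small heat shock protein, went from 4.52 ± 0.38 to 9.70 ± 0.21 on the log2 scale (SD, n = 2), a rise of 5.18 ± 0.29 (SE) or 36.3-fold (adjusted p = 4.05e-07, limma). AT1G53540, of the same class, rose by 4.43 ± 0.35, AT1G07400 by 3.73 ± 0.24 and AT5G51440, a mitochondrial small heat shock protein, by 3.62 ± 0.25. The DnaJ-domain gene AT1G71000 rose by 4.06 ± 0.24 and Fes1A (AT3G09350), which acts with HSP70, by 3.72 ± 0.23. The other large rises were AT5G54165 (4.65 ± 0.31), AT5G22140 (3.85 ± 0.25), the UDP-glycosyltransferase AT1G05675 (3.71 ± 0.53) and the AP2/ERF transcription factor AT1G71520 (3.54 ± 0.51). The largest falls were in the neighbouring leucine-rich-repeat receptor kinase genes AT1G51830 (-3.88 ± 0.32), AT1G51840 (-3.87 ± 0.49) and AT1G51850 (-3.64 ± 0.54). In WT the features of AT1G51830 and AT1G51840 had almost equal levels, 8.38 and 8.37 untreated and 4.50 and 4.51 with H2O2. In untreated CRF6oe they stood at 7.91 and 8.50. Which of these related genes gave the signal is uncertain. AT3G20380 fell by 3.54 ± 0.48, AT3G54040 by 3.18 ± 0.22 and AT1G52060 by 3.07 ± 0.61. Further falls were the extensin-like AT1G26250 at -3.29 ± 0.29, AT3G28550 at -3.21 ± 0.56, and the class III peroxidases AT4G30170 at -3.00 ± 0.29 and AT5G19890 at -2.95 ± 0.45. In all, 249 genes rose and 226 fell of 16548 tested, 475 together, and 1992 had an unadjusted p under 0.05. The arrays of the 2 groups did not overlap for 37.0% of genes, against 33.3% by chance. The count was 155 when only the 4 arrays compared were fitted, 312 with unnamed features tested too, and 188, 306 and 267 without untreated replicate 2, untreated replicate 1 and H2O2 replicate 1 of WT. AT3G28550 and AT1G52060 lost their calls when single arrays were left out, and the other 18 genes of this paragraph did not.

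Of 7 measured genes in the fixed list of heat shock proteins and factors, 6 rose with H2O2 in WT (6 adjusted over the list alone), with a list median of 3.62. Camera gave an adjusted p of 3.53e-22, and the adjusted p was 0.0017 with an estimated correlation. AT5G48570, a peptidyl-prolyl isomerase, rose by 2.81 and AT5G37670, a peroxisomal small heat shock protein, by 1.98, while ATHSP22.0 (AT4G10250) stood at 0.30 and did not pass. In the mitochondrial dysfunction list, 3 of 5 rose (3 adjusted over the list alone): AT5G51440, AT2G21640 (1.51 ± 0.25) and the alternative NADH dehydrogenase NDB2 (AT4G05020, 1.34 ± 0.23). The list's median was 1.34 (camera adjusted p = 7.91e-06, adjusted p = 0.0036 with an estimated correlation). Among dehydration genes 2 of 4 rose (2 adjusted over the list alone), COR15A (AT2G42540) by 2.33 ± 0.34 and KIN2 (AT5G15970) by 1.14 ± 0.23 (median 0.85, camera adjusted p = 2.7e-04, adjusted p = 0.0389 with an estimated correlation). Among antioxidant enzymes 2 of 5 rose (2 adjusted over the list alone), the monodehydroascorbate reductase ATMDAR2 (AT5G03630) by 1.29 ± 0.21 and the glutathione reductase GR1 (AT3G24170) by 0.80 ± 0.17. The median of this list was 0.05 and camera's adjusted p was 0.0115, with an adjusted p = 0.0549 with an estimated correlation. The glutathione S-transferases, which conjugate glutathione to reactive compounds, went both ways, and 2 of 9 rose (2 up and 1 down adjusted over the list alone). GSTU25 (AT1G17180) rose by 3.42 ± 0.48 and GSTF3 (AT2G02930) by 1.74 ± 0.43, but the list's median was -0.18 against a mean of 0.40 and a camera direction of up (adjusted p = 0.606). Of single regulators, the zinc finger factor STZ (AT1G27730) rose by 2.06 ± 0.33 and WRKY6 (AT1G62300) 2.82-fold (adjusted p = 0.0387), and the lateral organ boundaries factor LBD16 (AT2G42430) fell by 0.69 ± 0.17, the 1 call among 7 auxin genes (1 adjusted over the list alone, camera adjusted p = 0.745). None of 4 light-harvesting genes and none of 63 plastid-encoded genes was called by limma. Calls of WRKY6, GR1, NDB2, GSTF3, AT5G37670, KIN2 and LBD16 were lost when single WT arrays were left out, and that of STZ in the fit of only the 4 arrays compared.

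In crf6, AT2G29500 rose by 4.32 ± 0.29 with H2O2, AT1G71000 by 3.80 ± 0.24 and AT1G53540 by 3.63 ± 0.35. The beta-glucosidase BGLU28 (AT2G44460) rose by 3.93 ± 0.67 and AT5G16980 by 3.36 ± 0.60. AT1G51830 fell by 4.23 ± 0.32, AT1G51840 by 3.83 ± 0.49, the protein phosphatase gene AT4G32950 by 3.36 ± 0.28, AT2G20030 by 3.02 ± 0.17 and AT1G51850 by 2.95 ± 0.54. There were 143 rises and 180 falls, 323 genes in all, with 1563 at an unadjusted p under 0.05. The count was 203 with unnamed features tested too, and 97, 150, 139 and 161 without untreated replicate 2, untreated replicate 1, H2O2 replicate 1 and H2O2 replicate 2 of crf6. BGLU28, AT5G16980 and AT1G51850 lost their calls without single arrays. The difference between the H2O2 responses of crf6 and WT was called for 0 of 16548 genes by limma (lowest adjusted p = 1.00), with 480 at an unadjusted p under 0.05.

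In CRF6oe, small heat shock proteins also led the rises with H2O2, with AT1G53540 at 4.37 ± 0.35, AT1G54050 at 3.90 ± 0.30, AT1G52560 at 3.37 ± 0.28, AT2G29500 at 3.34 ± 0.29 and AT5G37670 at 3.15 ± 0.38. The largest falls were the extensin AT3G54580 at -4.12 ± 0.31, the peroxidase AT1G49570 at -3.31 ± 0.39, AT5G24200 at -3.23 ± 0.73 and AT3G28550 at -3.21 ± 0.56. The UDP-glycosyltransferase UGT84A3 (AT4G15490) fell by 2.95 ± 0.63. In all, 233 genes rose and 200 fell, 433 together, of which 264 changed at least 2-fold, and 3070 had an unadjusted p under 0.05. Without the dimmest 30% of features 122 rose and 204 fell. The count was 30 in the fit of only these 4 arrays, 185 with unnamed features tested too, and 95, 187 and 111 without untreated replicate 1, untreated replicate 2 and H2O2 replicate 1 of CRF6oe. AT5G24200, AT3G28550 and UGT84A3 lost their calls without single arrays.

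By gene group, the heat shock list rose in all 3 genotypes: in crf6 5 of 7 members rose (5 adjusted over the list alone, median 3.02, camera adjusted p = 2.64e-19) and in CRF6oe 7 of 7 (7 adjusted over the list alone, median 2.84, camera adjusted p = 6.14e-18). The adjusted p was 0.0029 and 0.0036 with an estimated correlation. AT5G37670 stood at 0.37 in crf6 and did not pass, and ATHSP22.0 rose by 1.70 in CRF6oe. The calls of AT5G48570 (2.04 in crf6, 2.16 in CRF6oe) were lost without single arrays. In the mitochondrial dysfunction list, 1 of 5 genes rose in crf6 (3 adjusted over the list alone, median 0.61, camera adjusted p = 3.5e-04) and 3 of 5 in CRF6oe (4 adjusted over the list alone, median 1.08, camera adjusted p = 7.42e-06). The adjusted p was 0.0124 and 0.0036 with an estimated correlation. NDB2 rose 2.83-fold in CRF6oe and AT5G09570 by 1.08, the latter lost without single arrays and the former, like ATHSP22.0, in the fit of only these 4 arrays. ATMDAR2 (1.08) and GR1 (0.71) rose in crf6, 2 of 5 antioxidant genes (2 adjusted over the list alone, camera adjusted p = 0.0220), both lost without single arrays, and the adjusted p was 0.0883 with an estimated correlation. In CRF6oe limma called 0 of these 5 (camera adjusted p = 0.108, and 0.0386 after quantile normalization). GSTU25 rose by 3.36 in crf6, where the list's camera adjusted p was 0.638, and stood at 1.13 without passing in CRF6oe, where GSTU18 (AT1G10360) rose by 0.95, lost without single arrays (camera adjusted p = 0.436). STZ rose by 2.40 ± 0.33 in crf6 and stood at 0.68 ± 0.33 in CRF6oe (adjusted p = 0.299), with a response difference between CRF6oe and WT of -1.39 ± 0.47 (adjusted p = 0.231). Limma called 0 of 4 dehydration genes in crf6 (camera adjusted p = 0.0332, adjusted p = 0.192 with an estimated correlation) and in CRF6oe (camera adjusted p = 0.996). LBD29 (AT3G58190) fell by 0.83 in CRF6oe, the 1 call of 7 auxin genes (camera adjusted p = 0.0362, adjusted p = 0.134 with an estimated correlation), and FMA (AT3G24140), a guard cell factor, fell by 0.90, both lost without single arrays. None of the following calls in some genotypes only was shown to differ by the interaction: against WT it was -1.61 ± 0.54 for AT5G37670 (adjusted p = 1.00) and -1.53 ± 0.48 for COR15A (adjusted p = 1.00) in crf6, and 1.41 ± 0.37 for ATHSP22.0 (adjusted p = 0.123), -2.29 ± 0.68 for GSTU25 (adjusted p = 0.164) and -0.95 ± 0.30 for ATMDAR2 (adjusted p = 0.191) in CRF6oe. COR15A and KIN2 differed between CRF6oe and WT, as given with that comparison below. All CRF6oe values are from the arrays that stood apart (r of at most 0.946 with the others).

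As a set, the heat shock genes rose less in crf6 than in WT by camera with the preset correlation, with a median difference of responses of -0.77 (camera adjusted p = 3.98e-05). No member's difference passed by itself, and the adjusted p was 0.0939 with an estimated correlation. Under H2O2 the 7 genes lay below WT in crf6 with a median of -0.87, 0 of them called over all genes and 6 adjusted over the list alone (camera adjusted p = 1.63e-07, adjusted p = 0.0665 with an estimated correlation). The mitochondrial dysfunction list differed in the same direction (median -0.47, camera adjusted p = 0.0202, adjusted p = 0.0939 with an estimated correlation).

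Over all genes, the H2O2 responses of WT and crf6, which share no arrays, correlated at r = 0.69, and those of WT and CRF6oe at 0.29. Genes are not independent replicates, so no p-value goes with these. Of the genes called in WT and crf6, 122 rose in both, 112 fell in both and 0 went opposite ways, where independent lists would share 2.15, 2.46 and 4.66. WT and CRF6oe shared 46 rises and 30 falls, with 3 genes opposite, against 3.51, 2.73 and 6.19. Of the 475 genes called in WT, 97.5% had the same sign in crf6 and 78.7% in CRF6oe.

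**Figure D2:**
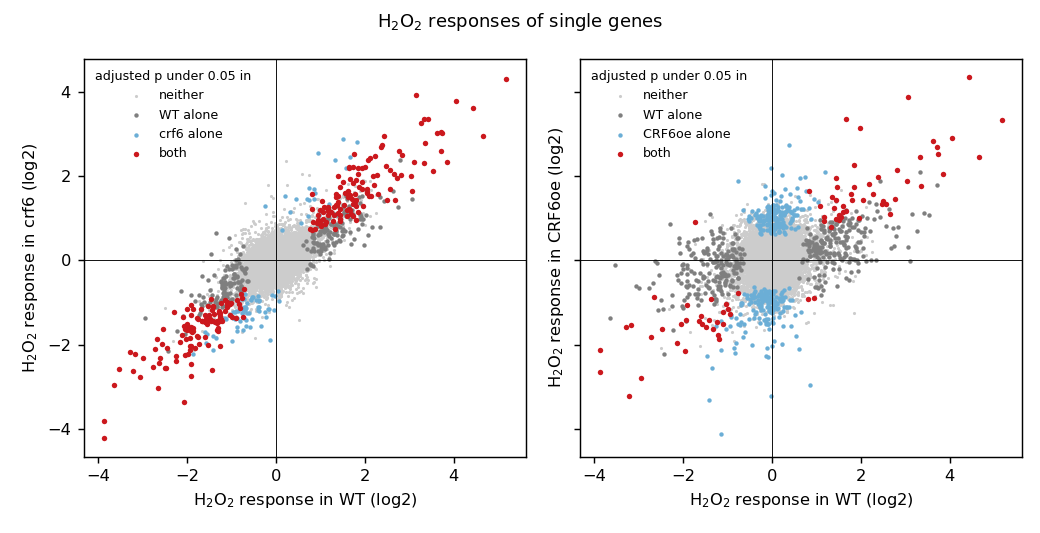
H2O2 response of each gene (log2, H2O2 minus untreated) in WT across and in crf6 (left) or CRF6oe (right) upwards, 1 point per gene, coloured by whether the gene was called in neither, in WT alone, in the other genotype alone or in both. The 234 genes called in WT and crf6 lie along the diagonal (r = 0.69 over all genes), whereas WT and CRF6oe share 79 calls (r = 0.29).

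In WT, BA raised type-A response regulators, early targets of cytokinin signalling that dampen it. ARR15 (AT1G74890) went from 3.61 ± 0.59 to 7.34 ± 0.34 (SD, n = 2), a rise of 3.73 ± 0.35 or 13.3-fold (adjusted p = 2.44e-04, limma), and RR16 (AT2G40670) rose by 2.19 ± 0.30 (adjusted p = 0.0048). These were the 2 measured members of their fixed list. UGT76C2 (AT5G05860), which conjugates glucose to cytokinins, rose 2.83-fold (adjusted p = 0.0075). Other rises were the glutaredoxin AT2G30540 (2.92 ± 0.34), the dirigent-like AT4G11190 (2.69 ± 0.22), AT5G26260 (1.97 ± 0.34), AT4G03610 (1.95 ± 0.21), the polygalacturonase-like AT5G14650 (1.90 ± 0.34), the beta-expansin EXPB3 (AT4G28250, 1.90 ± 0.30), AT2G32550 (1.81 ± 0.31) and AT1G28100 (1.75 ± 0.18). The largest falls were ATC (AT2G27550), a relative of the flowering regulator TFL1, at -3.25 ± 0.58, and the peroxidase AT4G08780 at -2.66 ± 0.42. AT4G00910 (-1.89), AT1G54890 (-1.83), AT1G05700 (-1.72), AT1G49470 (-1.71), AT1G29020 (-1.57), AT5G54020 (-1.51), AT2G20030 (-1.48) and the cell wall invertase homologue cwINV6 (AT5G11920, -1.39 ± 0.21) fell less. In all, 15 genes rose and 12 fell, 27 together, with 1195 at an unadjusted p under 0.05. The split was 12 and 16 after quantile normalization and 12 and 25 with each array centred on its median. The count was 9 in the fit of only these 4 arrays, 13 with unnamed features tested too, and 8, 11, 17 and 10 without untreated replicate 1, untreated replicate 2, BA replicate 1 and BA replicate 2 of WT. Of the 21 genes named, 7 kept their call whichever single array was left out: ARR15, AT2G30540, AT4G11190, AT4G03610, AT1G28100, AT1G29020 and AT2G20030, the last 2 of them lost in the fit of only these 4 arrays. None of the 8 fixed lists large enough to test had a gene called in WT with BA. The heat shock list's median was -0.34 (camera adjusted p = 0.0121, 2 lower adjusted over the list alone, adjusted p = 0.240 with an estimated correlation).

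The same cytokinin genes rose with BA in the other genotypes. ARR15 rose by 3.94 ± 0.35 in crf6 and 3.81 ± 0.35 in CRF6oe, RR16 by 2.77 ± 0.30 and 3.72 ± 0.30, AT4G11190 by 2.93 ± 0.22 and 3.19 ± 0.22, and UGT76C2 by 1.48 ± 0.21 and 1.79 ± 0.21. In crf6, AT2G30540 rose by 2.33 ± 0.34 and AT1G64590 by 2.31 ± 0.39, and AT1G29020 (-2.60 ± 0.17), AT4G08780 (-2.21 ± 0.42), AT4G32950 (-2.16 ± 0.28), AT3G05950 (-1.66 ± 0.25) and AT1G05700 (-1.66 ± 0.29) fell. In CRF6oe, AT5G43590 rose by 2.35 ± 0.31 and AT1G28100 rose 4.92-fold. AT4G14020 (-2.34 ± 0.35), the glutathione S-transferase GSTU20 (AT1G78370, -2.12 ± 0.33), AT1G68238 (-2.01 ± 0.38), AT3G18280 (-1.92 ± 0.31), AT1G04800 (-1.90 ± 0.23) and LBD29 (-1.04 ± 0.18) fell. GSTU20 was the 1 call of 9 glutathione S-transferases in CRF6oe (2 lower adjusted over the list alone, median -0.56, camera adjusted p = 0.0084, adjusted p = 0.0710 with an estimated correlation). LBD29 was the 1 call of 7 auxin genes there (2 lower adjusted over the list alone, median -0.36, camera adjusted p = 0.0084, adjusted p = 0.0802 with an estimated correlation). The 4 light-harvesting genes, with 0 called, had a median of -0.49 (2 lower adjusted over the list alone, camera adjusted p = 0.0103, adjusted p = 0.171 with an estimated correlation). In crf6 29 genes rose and 10 fell, 39 together (1049 at an unadjusted p under 0.05), a split of 25 and 15 with each array centred. In CRF6oe 17 rose and 18 fell, 35 together (1269 at an unadjusted p under 0.05), a split of 16 and 26 with each array centred. The crf6 count was 3 in the fit of only these 4 arrays, 23 with unnamed features tested too, and 11, 17, 15 and 12 without untreated replicate 1, untreated replicate 2, BA replicate 1 and BA replicate 2, and the CRF6oe count was 3, 15 and, without untreated replicate 1, 18. ARR15, RR16, AT4G11190 and AT1G29020 kept their calls in crf6 without each array in turn, and ARR15, RR16, AT4G11190, AT5G43590, AT1G28100, AT1G04800 and UGT76C2 did in CRF6oe, where the arrays stood apart from the rest. In the fit of only the 4 arrays compared, ARR15 and RR16 in crf6 and AT5G43590, AT1G28100, AT1G04800 and UGT76C2 in CRF6oe were not called.

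**Figure D3:**
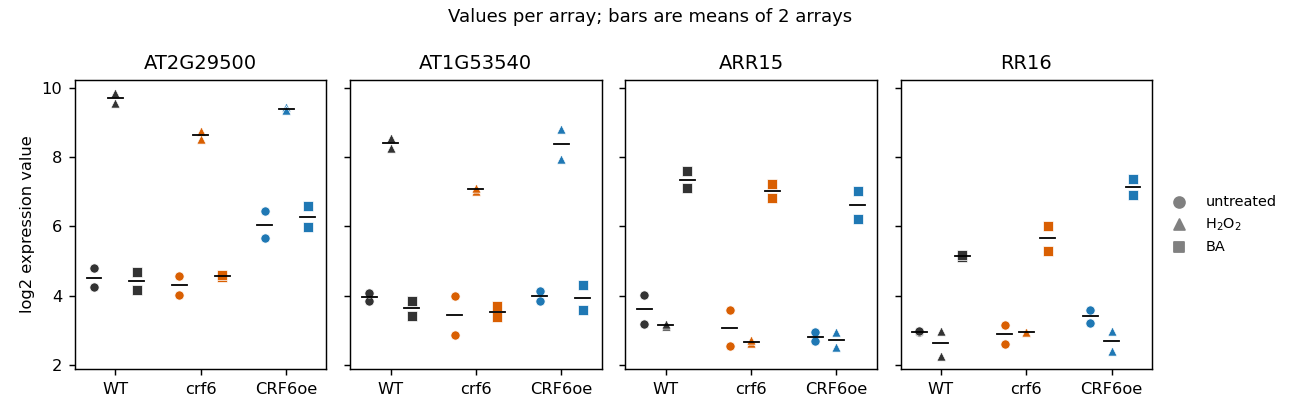
Log2 expression value of AT2G29500, AT1G53540, ARR15 and RR16 on each of the 18 arrays, by genotype across, with circles for untreated, triangles for H2O2 and squares for BA; short bars are means of 2 arrays. The heat shock genes are highest with H2O2 (AT2G29500 at 9.70, 8.62 and 9.39 in WT, crf6 and CRF6oe) and the response regulators with BA (ARR15 at 7.34, 7.01 and 6.62).

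No gene's BA response was called as different from that of WT, in crf6 (0 of 16548 by limma, 283 at an unadjusted p under 0.05) or in CRF6oe (0, with 760 at an unadjusted p under 0.05 and a lowest adjusted p of 0.679). Without CRF6oe untreated replicate 2 the latter count was 5, and without WT untreated replicate 2 it was 1. For RR16 the difference between CRF6oe and WT was 1.53 ± 0.42 (adjusted p = 0.999). BA responses correlated over genes at r = 0.53 between WT and crf6, with 9 shared rises, 4 shared falls and 0 opposite against 0.0263, 0.0073 and 0.0301 for independent lists. Between WT and CRF6oe the correlation was 0.29, with 7 shared rises, 1 shared fall and 0 opposite against 0.0154, 0.0131 and 0.0286.

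The H2O2 and BA responses in WT shared falls but no rises among called genes. Of 475 genes called for H2O2 and 27 called for BA, 9 were called for both, 0 rising in both, 7 falling in both and 2 going opposite ways, where independent lists would share 0.226, 0.164 and 0.385. Neither ARR15 (-0.46 ± 0.35) nor RR16 (-0.33 ± 0.30) was called with H2O2 in WT. UGT76C2 stood at -0.39 ± 0.21 with H2O2 in WT without passing and fell by 0.93 ± 0.21 in crf6 (adjusted p = 0.0381, lost without each of the 4 arrays in turn). The difference of that response between crf6 and WT was -0.54 ± 0.30 (adjusted p = 1.00). Over all genes the 2 responses of WT correlated at r = 0.16. They share the 2 untreated arrays, which alone gave r = 0.50 in simulated unchanged groups, and their covariance was 0.0219 against 0.0375 simulated, a difference of -0.0156. Part of any overlap may come from the shared controls, which were not split, as each part would have held 1 array. The correlation was 0.05 and 0.06 without BA replicate 1 and H2O2 replicate 2, and 0.32 and 0.34 without untreated replicates 2 and 1.

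Between crf6 and WT, limma called 0 genes in any single condition, with 855 untreated, 1141 with H2O2 and 746 with BA at an unadjusted p under 0.05. The lowest adjusted p was 0.105, 0.129 and 0.183. Without WT untreated replicate 2 or 1 the untreated count was 6 or 1, without WT H2O2 replicate 2 or crf6 H2O2 replicate 1 the H2O2 count was 19 or 1, and without WT BA replicate 2 the BA count was 1. As the mean over 3 conditions, 6 arrays against 6, single genes passed. The germin-like AT5G39120 was higher by 1.68 ± 0.29, the acyltransferase AT4G15390 by 1.67 ± 0.19, AT5G14650 by 1.63 ± 0.20, COR15B (AT2G42530) by 1.43 ± 0.23 and AT1G26250 was higher 2.65-fold. COR15A was higher by 1.54 ± 0.20 (adjusted p = 0.0055) and KIN2 by 0.65 ± 0.13, which made 2 of 4 dehydration genes (2 adjusted over the list alone, median 0.40, camera adjusted p = 0.0025, adjusted p = 0.167 with an estimated correlation). The anthocyanin gene DFR (AT5G42800) was higher by 1.17 ± 0.18 and LHCB4.3 (AT2G40100) by 0.74 ± 0.14, the 1 call among 4 light-harvesting genes (median -0.21, mean 0.01, camera direction down, adjusted p = 0.871). Lower in crf6 were the receptor kinase AT3G46370 (-1.41 ± 0.28), AT2G18690 (-1.25 ± 0.17), the lipid-transfer protein AT5G48490 (-1.22 ± 0.18), AT1G33610 (-1.18 ± 0.21), AT3G59880 (-1.14 ± 0.18) and STZ (-1.08 ± 0.19, adjusted p = 0.0265). In all 48 genes were higher and 47 lower, 95 together, with 2010 at an unadjusted p under 0.05. In the 12 WT and crf6 arrays alone 85 were called, and 7 with a random block for genotype and replicate number. Of the 95, 23 differed at least 2-fold, and 21 were called with unnamed features tested too. Without WT BA replicate 1 the count was 6, without crf6 BA replicates 2 and 1 it was 8 and 34, without WT untreated replicate 1 it was 13, without crf6 untreated replicates 2 and 1 it was 15 and 28, without crf6 H2O2 replicate 2 it was 18, without WT H2O2 replicate 1 it was 35, and without WT H2O2 replicate 2 it was 282. Of the 15 genes named, AT4G15390, AT5G14650, AT1G26250, AT2G18690 and COR15A kept their calls without each array in turn.

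CRF6oe differed from WT in a large share of the genes measured, in every condition. As the mean over 3 conditions, AT3G63052 was higher by 4.43 ± 0.14 (21.5-fold, adjusted p = 1.17e-10), AT2G38240, a 2-oxoglutarate-dependent oxygenase, by 4.06 ± 0.36, the ribosomal protein gene AT3G55750 by 3.86 ± 0.19, AT2G07738 by 3.53 ± 0.16 and AT5G54165 by 3.50 ± 0.18. The GRAS-family gene AT2G29065 was lower by 15.2-fold (-3.93 ± 0.15), AT1G14250 was lower as well (-3.81 ± 0.40), and AT2G23840, AT4G12900 and AT3G42628 stood at -3.25 ± 0.25, -3.13 ± 0.28 and -2.99 ± 0.15. Within single conditions AT3G63052 was higher by 4.76 ± 0.24 untreated, 4.13 ± 0.24 with H2O2 and 4.41 ± 0.24 with BA, and AT2G29065 stood at -4.42 ± 0.26, -3.45 ± 0.26 and -3.90 ± 0.26. The extensin AT3G54580 was higher by 3.87 ± 0.31 untreated, and the MADS-box gene AGL34 (AT5G26580) by 4.23 ± 0.41 with H2O2. COR15B was lower with H2O2 (-3.46 ± 0.39) and EXPB3 with BA (-3.87 ± 0.30). There were 1842 higher and 2332 lower genes untreated (4174 together), 2417 and 2463 with H2O2 (4880), 1938 and 2107 with BA (4045), and 3844 and 3827 over the mean (7671, or 46.4% of genes). Changes of at least 2-fold numbered 2034, 2101, 2086 and 1750. With each array centred the split was 1774 and 2889 with H2O2 and 2897 and 4440 over the mean. The count was 2213 with H2O2 when only these 4 arrays were fitted, and 2683, 3097 and 2635 in the single conditions without WT replicate 2 of that condition. Among 148 genes with several features, 18 had features called in opposite directions in the mean and 56 had only some of them called. All genes named here kept their calls without each array in turn, but genotype and array set are the same split, with an array correlation of at most 0.946 across it.

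Among the fixed lists, the signal of plastid-encoded genes was lower in CRF6oe, with 34 of 63 lower and 4 higher (38 and 4 adjusted over the list alone) and a median of -0.24 (camera adjusted p = 5.34e-06, adjusted p = 0.230 with an estimated correlation). The cRNA was primed from poly(A) tails, so this signal may not measure total plastid transcript levels, which was not tested. ycf4, ndhC and ndhG stood at -0.87 ± 0.08, -0.84 ± 0.09 and -0.81 ± 0.08, and rps18 was higher by 0.77 ± 0.15. Of 4 light-harvesting genes 3 were lower (3 adjusted over the list alone, median -0.81), with LHCB4.2 at -1.06 ± 0.13, LHB1B2 at -0.96 ± 0.16 and LHCB4.1 at -0.66 ± 0.10. Of 4 dehydration genes 3 were lower (3 adjusted over the list alone, median -0.87), COR15A at -1.98 ± 0.20, COR47 at -0.93 ± 0.13 and KIN2 at -0.81 ± 0.13. Of 7 auxin genes 3 were higher (3 adjusted over the list alone, median 0.78), WES1 by 1.44 ± 0.27, IAA29 by 1.12 ± 0.43 and LBD29 by 0.78 ± 0.10, and of 7 heat shock genes 3 were higher (3 adjusted over the list alone, median 0.24), AT1G07400 by 2.33 ± 0.14, AT2G29500 by 1.03 ± 0.17 and ATHSP22.0 by 0.57 ± 0.15. Camera gave each of these 4 lists an adjusted p of 0.0486, and the adjusted p was 0.274, 0.230, 0.230 and 0.336 with an estimated correlation. The antioxidant enzymes split into 2 higher and 3 lower (camera adjusted p = 0.348), with the thylakoid ascorbate peroxidase TAPX at -1.12 ± 0.10, and the glutathione S-transferases into 3 and 3 (camera adjusted p = 0.937), with GSTU26 at 1.74 ± 0.28 and GSTU25 at -1.60 ± 0.28. In the mitochondrial dysfunction list 1 of 5, AT5G09570, was higher (camera adjusted p = 0.348). RR16 was higher (0.83 ± 0.17), and ARR15 (-0.64 ± 0.20), UGT76C2 (-0.63 ± 0.12) and UGT76C1 (-0.63 ± 0.12) were lower. STZ was higher by 1.03 ± 0.19, and the clock gene GI (AT1G22770, -1.44 ± 0.12) and the pyruvate decarboxylase PDC2 (AT5G54960, -1.30 ± 0.15) were lower. Each of these differences lies along the same split as the array sets (r of at most 0.946 across it). Over the comparisons of gene lists, only the calls of the heat shock and mitochondrial dysfunction lists with H2O2 in the 3 genotypes, and of the dehydration list with H2O2 in WT, held with an estimated correlation.

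The response to H2O2 itself differed between CRF6oe and WT for 95 genes, 55 more positive and 40 more negative in CRF6oe, with 2240 at an unadjusted p under 0.05. AT5G43520, which went from 6.53 ± 0.01 to 4.22 ± 0.57 with H2O2 in WT and from 4.47 ± 0.15 to 5.34 ± 0.01 in CRF6oe (SD, n = 2), differed by 3.17 ± 0.40 (adjusted p = 0.0059). AT3G20380 differed by 3.43 ± 0.68, AT1G53610 by 2.64 ± 0.31, AT1G05700 by 2.63 ± 0.41 and the serine carboxypeptidase-like scpl28 (AT2G35770) by 2.63 ± 0.36. More negative in CRF6oe were AT2G41730 (-3.10 ± 0.65), AT3G54580 (-2.97 ± 0.44), AT4G08555 (-2.73 ± 0.57), AT1G02470 (-2.71 ± 0.52) and the UDP-glycosyltransferase UGT73B3 (AT4G34131, -2.37 ± 0.46). COR15A (-2.31 ± 0.48) and KIN2 (-1.84 ± 0.33) were 2 of 4 dehydration genes (2 adjusted over the list alone, median -0.94, camera adjusted p = 0.0375, adjusted p = 0.362 with an estimated correlation). The split was 51 and 25 after quantile normalization. By absolute size 68 of the 95 responses were smaller in CRF6oe and 27 larger, and 66 had opposite signs in CRF6oe and WT. These counts are read on genes chosen by this difference. Over all genes the SD of responses was alike (0.433 in CRF6oe and 0.442 in WT). The median absolute response was larger in CRF6oe, at 0.245 against 0.186 in WT. The count was 1 in the fit of only the 8 arrays compared, 10 with unnamed features tested too, and 12, 13, 21, 36 and 30 without CRF6oe untreated replicate 1, CRF6oe H2O2 replicate 1, WT untreated replicate 2, WT untreated replicate 1 and WT H2O2 replicate 1. AT5G43520, AT1G53610 and scpl28 kept their calls without each array in turn but not in the fit of only the 8 arrays.

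A gene controlled by CRF6 in a fixed direction would move oppositely in crf6 and CRF6oe. Within single conditions the count could only be 0, since limma called 0 genes in crf6 there, so it does not bear on this. Over the mean of 3 conditions, 63 of the 95 genes called in crf6 were also called in CRF6oe, 7 higher in both, 19 lower in both and 37 opposite, where independent lists would share 11.2, 10.9 and 22.0. By these means STZ was lower in crf6 and higher in CRF6oe, and COR15A and KIN2 were higher in crf6 and lower in CRF6oe. The CRF6oe differences were not alike in every condition. With H2O2 alone STZ was not called higher in CRF6oe, and COR15A and KIN2 had more negative H2O2 responses there than in WT (-2.31 and -1.84). The crf6 calls of STZ and KIN2 were lost without single arrays and in other settings, and with the random block given above 7 crf6 calls were left of 85. The contrasts share the 6 WT arrays and correlated at r = -0.09 over genes, where unchanged groups gave r = 0.50. Their covariance was -0.0117 against 0.0125 simulated, a difference of -0.0242. Shared controls push both contrasts the same way, so part of the calls the same way in both may come from them.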

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

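The response to H2O2 differed between CRF6oe and WT for 95 genes, a difference between groups that was tested directly as an interaction. The genes named are AT3G20380 (3.43), AT5G43520 (3.17), AT1G53610 (2.64), AT1G05700 (2.63) and scpl28 (2.63), all more positive in CRF6oe, and AT2G41730 (-3.10), AT3G54580 (-2.97), AT4G08555 (-2.73), AT1G02470 (-2.71), UGT73B3 (-2.37), COR15A (-2.31) and KIN2 (-1.84), all more negative. A separate signal lies in features outside the gene comparisons. In all, 9 features with no gene name, identical on every array, were higher in crf6 than in WT by 4.80 ± 0.27 untreated, 5.05 ± 0.27 with H2O2 and 4.87 ± 0.27 with BA (adjusted p = 1.88e-06, 1.02e-06 and 1.56e-06). Their level was 9.03 in untreated crf6, 4.23 in untreated WT and 5.03 in untreated CRF6oe, and they were singled out after the values were seen.

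For the 95 genes, the test on genes raised by BA was chosen only after seeing the result, and the other tests were written before it. Over 323 genes called for H2O2 in crf6, the median response of CRF6oe was 0.312 of that of crf6, against 0.971 in WT. The CRF6oe median was low in rising genes (0.393) and in falling genes (0.242), as smaller fold changes on the CRF6oe arrays would give. Of the 323 genes, 21.4% had the opposite sign to crf6 in CRF6oe, against 0.9% in WT. Smaller fold changes alone reverse no sign, but the spread between arrays can turn the sign of a small response. The share of reversals that this would give was not computed, so the 21.4% cannot decide. Over 29 genes raised by BA in crf6 the ratio was 0.681 in CRF6oe (95% bootstrap interval 0.601 to 0.846) and 0.681 in WT. An equal compression of all fold changes on the CRF6oe arrays would give 0.256, so these values argue against that. The interval resampled genes, which are not independent replicates. No H2O2 array enters this ratio, so it cannot exclude smaller fold changes on the H2O2 arrays of CRF6oe alone. WT H2O2 replicate 1 was not the array on which most calls rested, since the count without it was 30, against 21 without WT untreated replicate 2 and 12 without CRF6oe untreated replicate 1, but most calls did need each of these arrays. A different response to H2O2 because of the CRF6oe genotype remains open and was not tested apart from the array set.

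For the CRF6oe arrays as a whole, the test on the top of the value range was chosen only after seeing the result, and the other 2 were written before it. If the arrays vary independently, an accidental split is unlikely. Among 100 splits of the 12 CRF6oe and WT arrays within conditions, only the real one called as many as its 7023 genes. The highest other called 1790, and 1 of 100 is the lowest share these splits can give. The top 0.1% of values on an array began at 13.42 to 13.59 in CRF6oe and 13.19 to 13.34 in the others. The gap of 0.0782 was less than the spread within either set. The highest value on an array was 14.16 to 14.26 in CRF6oe and 13.90 to 13.99 in the others, further apart than the spread of either set. Whether separate processing or normalization caused these gaps cannot be told. Defensin-like peptide genes, which were taken to be silent in seedlings without a test of that here, were called for 16.0% (12 of 75), against 46.4% of all genes, which neither excludes nor requires an array-wide hybridisation difference. An effect of the CRF6oe genotype on many genes remains open and cannot be told apart from the array set.

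For the 95 genes that differed between crf6 and WT over 3 conditions, both tests were written before their results were seen. If the arrays vary independently, an accidental split is unlikely. Among 100 splits of the 12 arrays, only the real one called as many genes as the 85 of the fit without CRF6oe. The highest other called 1, and 1 of 100 is the lowest share these splits can give. With a random block for genotype and replicate number, the count fell from 85 to 7 at an estimated correlation of 0.112, which is in line with arrays of 1 genotype and replicate number varying together. The splits ignore such shared variation, so they say nothing about it, and the block also leaves fewer independent units. An effect of the crf6 mutation on these genes remains open and was not tested further.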

How the results depend on the processing

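No correlation of responses and no log2 change of a gene followed through the alternatives changed sign, and the 10 top genes of each CRF6oe against WT contrast kept their calls. Majorities near even did turn, among them these: BA in WT had 15 genes higher and 12 lower, but 12 and 16 after quantile normalization and 12 and 25 after centring, and CRF6oe against WT over 3 conditions went from 3844 and 3827 to 2897 and 4440 after centring, and H2O2 in CRF6oe from 233 and 200 to 122 and 204 without the dimmest 30% of features. Medians of some lists near 0 turned sign too. Quantile normalization, centring, leaving out dim features and the intensity trend moved no total count by more than 1.5-fold. Counts in 1 direction moved more in some cases: besides the falls with BA in WT, the more negative H2O2 responses of CRF6oe against WT went from 40 to 25 after quantile normalization, and besides the rises with H2O2 in CRF6oe the falls with BA in crf6 went from 10 to 5 without the dimmest 30% of features. Not every call in the text was followed through the alternatives. Over pairs of a followed gene call and a left-out array, the call was kept in 706 and lost in 266, and of the followed calls 114 were kept and 67 lost in the fit of only the arrays compared. With only those arrays the counts were 155 for H2O2 in WT, 30 for H2O2 in CRF6oe, 9, 3 and 3 for BA in WT, crf6 and CRF6oe, 2213 for CRF6oe against WT with H2O2 and 1 for the H2O2 response of CRF6oe against WT, where fewer arrays estimate the spread. With unnamed features tested too, they were 312, 203 and 185 for H2O2 in WT, crf6 and CRF6oe, 13, 23 and 15 for BA, 21 for crf6 against WT over 3 conditions and 10 for the H2O2 response of CRF6oe against WT. At a threshold of 2-fold, which can only remove genes, they were 264 for H2O2 in CRF6oe, 2034, 2101 and 2086 for CRF6oe against WT untreated, with H2O2 and with BA, 1750 over 3 conditions, and 23 for crf6 against WT over 3 conditions. Without the dimmest 30% of features the correlation of responses was 0.77 for H2O2 in WT and crf6, 0.61 for BA in WT and crf6 and 0.34 for BA in WT and CRF6oe, and the cause was not tested.

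Leaving out 1 array at a time, which leaves fewer arrays, gave 188 to 525 genes for H2O2 in WT, 97 to 161 in crf6 and 95 to 496 in CRF6oe, and 8 to 17, 11 to 17 and 18 to 45 for BA. For crf6 against WT it gave 0 to 6 untreated, 0 to 19 with H2O2, 0 to 1 with BA and 6 to 282 over 3 conditions. For CRF6oe against WT it gave 2683 to 3093, 3097 to 4313, 2635 to 3106 and, over 3 conditions, 6956 to 7685. The H2O2 response of CRF6oe against WT ranged from 12 to 100 and the BA response from 0 to 5, and those of crf6 against WT stayed at 0. Counts that rose with fewer arrays have a cause that was not tested. The correlation of responses ranged from 0.053 to 0.34 for H2O2 and BA in WT, 0.57 to 0.68 for H2O2 in WT and crf6, 0.21 to 0.31 for H2O2 in WT and CRF6oe, 0.42 to 0.48 for BA in WT and crf6 and 0.21 to 0.30 for BA in WT and CRF6oe. The labels do not say whether replicate numbers pair samples. Deviations of the replicates correlated over 0.1 in 7 of 36 pairs of groups, at -0.20 to 0.33 over all pairs and 0.22 to 0.33 in the 3 pairs of WT groups, and with the replicate number as a block the count for crf6 against WT over 3 conditions was 157. The cause was not tested. With an estimated correlation, 34 results of the fixed lists that camera had called were no longer called. The other 110 stayed the same, most of them called with neither correlation. The split of WT and CRF6oe arrays called 7023 genes against 1790 for the highest other split, and that of WT and crf6 arrays 85 against 1. The CRF6 level and its alternatives were not run, since no named feature was paired with that gene.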

Other observations

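Gene families defined by symbol or position were added after the first results had been seen. In CRF6oe against WT over 3 conditions, autophagy genes, whose products form the vesicles that carry cell contents to the vacuole, were higher. APG8H was higher by 1.74 ± 0.12, ATG8B by 1.68, ATG8G by 1.62 and ATG8C by 1.00, and of 10 genes 8 were higher and 0 lower (9 and 0 adjusted over the list alone, median 0.95, camera adjusted p = 4.48e-04). The adjusted p was 0.318 with an estimated correlation. With H2O2 in CRF6oe 4 of the 10 fell, ATG8B by 1.29 ± 0.30, APG8A by 0.97, ATG8C by 0.93 and ATG8D by 0.90 (4 adjusted over the list alone, median -0.40, camera adjusted p = 1.14e-04, adjusted p = 0.613 with an estimated correlation). The PRA1 family of vesicle traffic proteins was higher in CRF6oe for 10 of 16 genes (10 adjusted over the list alone, median 0.51, camera adjusted p = 0.0027, adjusted p = 0.268 with an estimated correlation), and IQ-domain calmodulin-binding genes were lower for 9 of 17 and higher for 1 (10 and 1 adjusted over the list alone, median -0.35, camera adjusted p = 0.0048, adjusted p = 0.268 with an estimated correlation). Nuclear copies of mitochondrial genes on chromosome 2 were higher for 28 of 42 and lower for 6 (28 and 6 adjusted over the list alone, median 1.06, camera adjusted p = 7.98e-07, adjusted p = 0.402 with an estimated correlation), with AT2G07738 at 3.53, AT2G07691 at 3.34 and AT2G07674 at -1.62. Features for such copies may also bind the mitochondrial transcripts, which was not tested. These 4 families differ along the same split as the array sets (r of at most 0.946 across it).

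With H2O2 in crf6, EXPB3 fell by 1.25 ± 0.30, EXPA4 by 1.11 ± 0.26 and EXPA9 by 0.86 ± 0.18, which made 3 of 22 expansins, proteins that loosen cell walls (5 lower and 1 higher adjusted over the list alone, median -0.28, camera adjusted p = 0.0030, adjusted p = 0.390 with an estimated correlation). In WT the ubiquitin ligase PUB23 rose with H2O2 by 1.67 ± 0.36, the 1 call among 10 U-box genes (3 adjusted over the list alone, median 0.31, camera adjusted p = 0.0143, adjusted p = 0.818 with an estimated correlation). Of 51 UDP-glycosyltransferases 3 had a more negative H2O2 response in CRF6oe than in WT (6 lower and 3 higher adjusted over the list alone, median -0.25, camera adjusted p = 0.0056, adjusted p = 0.263 with an estimated correlation).

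A hypothesis was that H2O2 lowers genes that cytokinin raises. The prediction was written before the test, and the comparison with genes lowered by BA was chosen only after seeing the result. The 34 genes raised by BA in crf6 or CRF6oe, arrays that share no control with the H2O2 response of WT, had a median H2O2 response in WT of -0.29. Of these, 31 were negative and 3 positive, and 1 was called, and the rotation test fry found a fall of the set. Its p is not printed because it depends on the order in which the groups enter the fit, and the call is given for a single order. The 27 genes lowered by BA in those genotypes lay below 0 as a set too, with a median of -0.23, 20 negative and 7 positive. Of these, 9 were called, all as falls, and the rest did not pass. The fall is in line with the hypothesis but is not specific to the genes that cytokinin raises, and an opposing action of H2O2 on cytokinin signalling was not shown.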
